A study of Mus musculus with 4 samples.

How the data were processed

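Total RNA from 4 mouse hippocampus samples was measured on Affymetrix MG_U74Av2 (Murine Genome) arrays, 1 array per sample; the design is known from the platform that the probe annotation names. Such an array reads each transcript with 1 or more probe sets of short oligonucleotides. The deposited values are intensities on a linear scale, never below 0, for 12488 probe sets per array, of which 66 are controls. The software and settings that made these intensities before deposit are not given in the sources used here. From the deposited values, the mean of each array after leaving out the lowest and highest 2% of its probe sets was 250.1 units, so that the arrays had been scaled to a shared level before deposit. Detection calls and probe-level data were not used here. The number of arrays limits the precision, and a low signal cannot be told from background without such calls. The label of each sample names the tissue and holds an identifier whose meaning is not given, and all 4 samples formed 1 group, with replicate numbers that name samples and pair none.

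Control probe sets were left out, and the arrays were quantile normalized with limma 3.58.1 in R 4.3.3. Normalized values below their 25th percentile (27.7 units) were set to it, and values were taken to log2. This floor understates the range of genes with low signal, and a range that involves it is given as a lower bound. Probe sets with a mean above the median of all means were analysed, 6210 of 12422. Among all probe sets, 10833 had 1 gene symbol in the annotation, 396 had several and 1193 had none, and only the first kind was named. The symbols of 10817 probe sets were taken from the RefSeq gene table of mouse assembly GRCm38.p6 through the Entrez identifier. The analysed probe sets covered 4824 named genes, each represented in gene lists by its probe set with the highest mean. Where other analysed probe sets of a named gene existed, their highest sample differed for Mag, C1qb, Prkcd, Mef2c, Cct3, H2-D1 and Kcnj9. Probe sets of related sequences, such as MHC class I genes, globins and Erdr1, can detect more than 1 gene.

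Excess variance was tested for each probe set against the intensity trend of the variance, fitted robustly with limma's empirical Bayes functions, with a one-sided F test on 3 residual and 5.06 prior degrees of freedom and Benjamini-Hochberg adjustment at 0.05. Pairs of samples were compared by correlation across probe sets and by the median absolute log2 difference. For 26 gene lists, the median over genes of the log2 signal in a sample minus the mean of the other 3 samples was ranked among 10000 random lists matched on mean signal in 20 bins. A list stood apart in a sample when it lay outside the central 99% of them, and lists with fewer than 4 analysed genes were not tested. The spread of a list, the median log2 ratio of each gene's SD to the trend, was ranked in the same way. The percentiles describe these samples and are not p-values. The gene lists, the tests described so far with their thresholds, and the rule for named genes were set before the data were examined. The variance test was also adjusted over the analysed genes of a list alone. That adjustment was not in the plan and was not corrected across the 26 lists. Other tests chosen after values had been seen are named as such where they are given. The lists were written from general knowledge of brain cell types, bordering tissues, stress responses, and genes reported to vary between inbred strains.

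Genes were named by a rule with 5 parts. It took the genes with the largest range past the variance test, of which there were 0, the first 2 analysed members of each list, the member of each list with the largest range, the measured sex-linked genes, and up to 4 members with the largest deviation where a list stood apart. Erdr1, Gas5, Jun, Egr1 and Tsc22d3 were added outside this rule, after the data had been seen, because they ran against the median of their list or hardly followed it. Genes of the immediate early and glucocorticoid lists with a mean too low for analysis were also named after the data had been seen. Signals in the text are quantile normalized units before the floor, with SD over 4 samples.

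The variance test was tested on simulated data with 200 of 6210 probe sets changed. A change between 2 and 2 samples was recovered in 0% of probe sets at 4-fold, 77% at 8-fold and 100% at 16-fold, and a change in 1 sample in 0% at 8-fold and 93.5% at 16-fold. The test against the local median recovered 0% at 4-fold in both designs, and at 8-fold 98% and 78.5%, with 9 and 6 false calls where the main test made 0. Ratios of 3' to 5' signal were computed from deposited signals, and a ratio over a 5' signal below the floor was taken as a lower bound, a choice made after the data had been seen. In 20 simulations without differences, in which probe sets varied independently, a mean of 1.05 of 96 pairs of list and sample stood apart, and the highest number was 3. Alternatives covered the scaling of arrays, the floor, the signal filter, the variance model, the probe set taken per gene and the omission of each sample in turn, and the deposited scale without further normalization was added after the data had been seen. Figures were drawn with matplotlib 3.10.9.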

Results

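Gene expression was profiled in 4 samples of mouse hippocampus, the forebrain structure that holds the dentate gyrus and the pyramidal cell fields, with 1 Affymetrix Murine Genome array per sample and total RNA as the starting material. The series title calls the samples replicates, and the labels place them in a single group without a strain, sex, age or treatment. The question addressed was therefore how far replicate hippocampus samples differed and in which genes, and no comparison between groups was made. No label states whether the samples came from separate animals. The spread between them may in part be technical. Each p-value only compares the spread of a probe set with that of other probe sets of like signal. The samples are called 1 to 4, numbers that serve only as names. Each array gave signals for 12422 probe sets besides 66 controls, and the 6210 probe sets with a mean signal above the median were analysed. Signals are given in normalized array units, and the number of arrays limits the precision of every value.

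Samples 1, 2 and 3 resembled one another more closely than any of them resembled sample 4. Across the analysed probe sets, Pearson's r ranged from 0.907 for samples 1 and 4 to 0.949 for samples 1 and 3, and Spearman's rho ranged from 0.889 to 0.938. These correlations are across probe sets, which are not independent replicates. The median absolute log2 difference between 2 samples was lowest for samples 1 and 3, at 0.21, and highest for samples 1 and 4, at 0.30. The number of probe sets that differed at least 2-fold was 205 for samples 1 and 3 and 462 for samples 1 and 4. The ratio of 3' to 5' signal of control transcripts, which rises when RNA or its cDNA copy is less complete, was highest in sample 4 for 4 of 5 transcripts. For beta-actin (Actb) this ratio was 1.84, 1.64, 1.51 and 2.03 in samples 1 to 4, and for Gapdh it was 0.887, 0.864, 0.981 and 1.15. For pyruvate carboxylase it was 2.62, 1.81, 3.03 and 3.16, so that sample 4 lay close to sample 3. For 18S, a ribosomal RNA and not an mRNA, it was 5.01, 4.65, 3.02 and 6.42. For the transferrin receptor the ratio was 1.41, 2.40 and 3.36 in samples 1 to 3 and at least 2.71 in sample 4, whose 5' signal of 10.4 deposited units lay below the floor of 27.7 units, so that its highest sample is not settled. The 9 probe sets for bacterial and phage transcripts that are added during array preparation were highest in sample 3 in 9 of 9 cases, and lowest in sample 4 in 6 cases and in sample 2 in 3 cases.

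**Figure D1:**
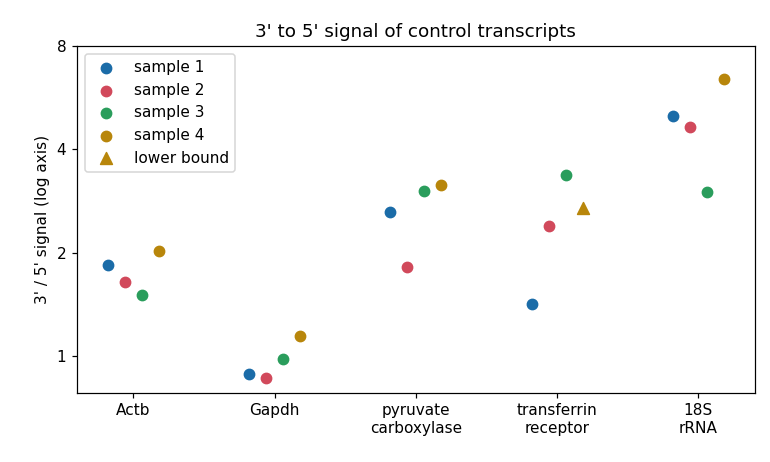
Ratio of 3' to 5' signal (log axis, no unit) for 5 control transcripts on each array, computed from deposited signals; each point is 1 sample and no error bar applies. The gold points of sample 4 lie highest for 4 of the 5 transcripts, from 1.15 for Gapdh to 6.42 for 18S rRNA; the triangle is a lower bound of 2.71 for the transferrin receptor, computed with the floor as the 5' signal.

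Most genes varied little between the samples. The median range over the 4 samples was 0.53 log2 units, a 1.45-fold span, and 3466 of 6210 probe sets (55.8%) spanned less than 1.5-fold. A range of at least 2-fold was found for 944 probe sets (15.2%). This number was 457 when sample 4 was left out, and 697, 735 and 687 without samples 1, 2 and 3. A range over fewer samples can only be equal or smaller, so part of each fall follows from the omission itself. No probe set had a variance above the intensity trend after adjustment (limma, one-sided F test with Benjamini-Hochberg adjustment, smallest adjusted p = 0.356, and 0.0531 to 0.900 with the other variance tests tried). An unadjusted p under 0.05 was found for 349 probe sets (5.62%), against 5.80% in simulated data without differences. The trend and the prior were fitted to these same variances, so this share follows largely from the fit. The test compares a probe set with others of like signal and does not show how much of the variation is chance. The other variance tests tried also gave 0 probe sets after adjustment, with 320, 321 and 335 at an unadjusted p under 0.05. In simulated data, 0 of 200 probe sets changed 4-fold were recovered by this test or by a test against the local median of the variance; of those changed 8-fold between 2 and 2 samples, 77% and 98% were recovered, and of those changed 8-fold in 1 sample, 0% and 78.5%. The values of single genes that follow are therefore given as measured, and no single gene is called variable on the basis of all probe sets. Among gene lists, 17 of 96 pairs of a list and a sample lay outside the central 99% of random lists of like signal, where 0.96 were due if genes varied independently. Genes of a list can vary together, some lists share genes, and the deviations of a list in the 4 samples depend on one another. The 17 pairs are therefore not separate trials, and their excess over 0.96 does not exclude ordinary variation shared by related genes. These pairs came from 8 of the 24 lists that could be tested. The spread over the samples was wide for 5 lists and narrow for 0, where 0.24 were due in both directions together if genes varied independently.

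**Figure D2:**
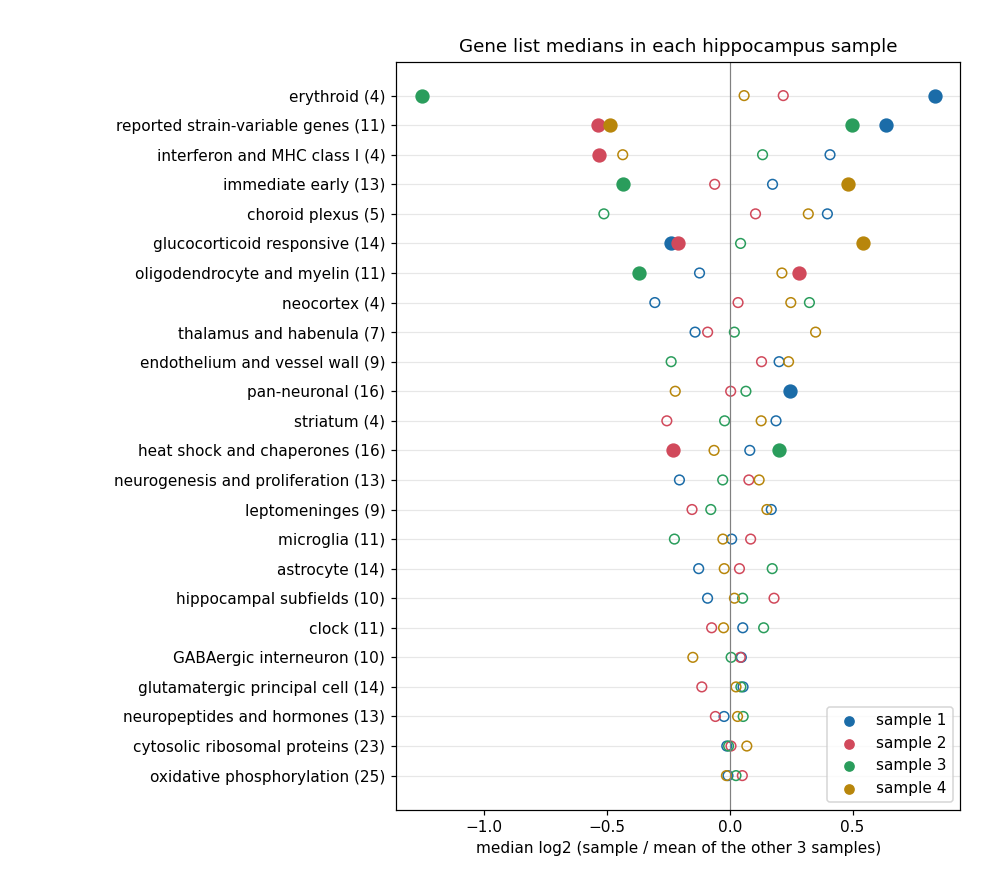
Median over each gene list of the log2 signal in a sample minus the mean of the other 3 samples (horizontal axis, log2 units), with the number of analysed genes in parentheses. Filled points lie outside the central 99% of random lists, open points inside; the erythroid list spans from -1.25 in sample 3 to 0.83 in sample 1.

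The list that set the samples apart most broadly held genes that, as background knowledge, have been reported to differ in expression between inbred mouse strains. Its 11 analysed genes had a median log2 deviation of 0.63 in sample 1 and 0.50 in sample 3, and of -0.54 in sample 2 and -0.49 in sample 4, each outside the central 99% of random lists. Sample 4 was also the sample with the highest 3' to 5' ratio for 4 of 5 control transcripts, and 89 probe sets lay far below every other sample in it. Glyoxalase 1 (Glo1), which detoxifies methylglyoxal, gave 1675, 872, 1438 and 838 units in samples 1 to 4, with a mean of 1206 ± 417 (SD, n = 4). The heme synthesis enzyme Alad gave 545, 248, 619.8 and 196 units (402 ± 212, SD, n = 4), and the GABA-A receptor subunit Gabra2 gave 359.7, 136, 491 and 232 units. The potassium channel subunit Kcnj9 gave 694, 266, 601 and 169.6 units, although its second analysed probe set was highest in another sample. Pam, an enzyme that amidates neuropeptides, gave 372, 110.1 and 345 units in samples 1 to 3 and lay below the floor of 27.7 units in sample 4, so that its range was at least 13.4-fold. Nnt (103, 71.2, 99.8 and 142 units) and St3gal4 (103, 286, 169 and 50.8 units) followed other orders, and Erdr1 (1215, 6078, 3093.5 and 4838 units) and Gas5 (1277, 1719, 1165 and 2256 units) ran against the list's median, lower in samples 1 and 3 than in samples 2 and 4. Adjusted over the list alone, 9 of 11 genes passed the variance test, against 0 over all probe sets, and the list's spread lay above that of each of 10000 random lists. Here and below, an adjustment over a list alone was not in the plan and was not corrected across the 26 lists. Such a count describes genes within their list and does not call a gene variable. The deviation no longer stood apart in sample 2 without sample 1 (-0.28), nor in sample 4 without sample 1 (-0.25), without sample 3 (-0.36) or with the median over a gene's probe sets (-0.31).

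Of 4 sex-linked genes measured, 2 had a mean high enough for analysis, and their signals ran in opposite directions. Xist, the RNA that silences an X chromosome in female cells, gave 22.2, 307, 659 and 42.0 units in samples 1 to 4. Eif2s3y, a translation factor gene of the Y chromosome, gave 232, 6.22, 26.1 and 190.5 units. Values under the floor of 27.7 units, 1 for Xist and 2 for Eif2s3y, have no order, and the ranges were at least 23.8-fold for Xist and at least 8.40-fold for Eif2s3y. Adjusted over the list alone, 2 of 2 genes passed the variance test. The Y-linked genes Uty (47.5, 7.03, 6.97 and 13.7 units) and Kdm5d (8.93, 26.0, 11.7 and 16.9 units) were below the analysed range, with Uty above the floor in sample 1 only. The labels give no sex for any sample, and none was assigned.

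Most analysed genes from the lists that respond to neuronal activity and to glucocorticoids were high in sample 4. This sample had the highest 3' to 5' ratio for 4 of 5 control transcripts. Among 13 analysed immediate early genes, 12 were above the mean of the other samples in sample 4, with a median log2 deviation of 0.48, and 10 were below it in sample 3, with a median of -0.43. Jun was the exception in sample 4 (347, 360, 398 and 203 units in samples 1 to 4), and Egr1 was above by only 0.0129 log2 units. The spread of this list was 1.57 times the trend, outside the central 99% of random lists. The transcription factor genes Fos and Junb gave 157, 55.5, 67.7 and 354 units and 293, 189, 164 and 573 units in samples 1 to 4. Fosb gave 291, 160.5, 269 and 379 units, and the orphan receptor gene Nr4a1 gave 294, 246, 261 and 447 units. Dusp6, a phosphatase of the ERK pathway, was lowest in sample 3 (669, 537, 348 and 682 units), as was the synaptic pentraxin Nptx2 (124, 225, 102 and 182 units). Of 14 analysed glucocorticoid-responsive genes, 10 were above the others in sample 4, with a median of 0.54, while 12 were below in sample 1 (-0.24) and 12 were below in sample 2 (-0.21). The kinase gene Sgk1 gave 439.9, 472, 528 and 1237 units, a 2.59-fold deviation in sample 4, and Klf9 gave 639, 779, 1426 and 1545 units. Fkbp5, a cochaperone of the glucocorticoid receptor, gave 533, 693, 707 and 887 units, Zbtb16 gave 758, 839, 943 and 1468 units, and Pdk4 gave 115, 74.5, 93.5 and 176 units. The inhibitor of NF-kappaB, Nfkbia, gave 262, 330.0, 394 and 519.6 units, whereas the cell cycle inhibitor Cdkn1a was highest in sample 3 (96.7, 64.1, 257 and 74.6 units). Tsc22d3, whose mean was too low for analysis, was lowest in sample 4 (75.6, 130, 97.7 and 29.15 units), close to the floor. Sult1a1, also too low for analysis, was above the floor in sample 4 only. Nr3c1 was below the mean of the other samples there. Among such immediate early genes, Fosl2, Atf3, Homer1 and Ptgs2 were below that mean in sample 4, and Egr2 and Klf4 above it. Klf2 was under the floor. Adjusted over the list alone, 0 genes of either list passed the variance test. The immediate early list no longer stood apart in sample 4 without sample 3 (0.33) or in sample 3 without the signal filter (-0.23), and its wide spread was lost without sample 3 (0.48) or sample 4 (0.47). The low glucocorticoid values were lost without the signal filter in samples 1 and 2 (-0.15 and -0.19) and without sample 4 (-0.18 and -0.01), and that of sample 2 also without sample 3 (-0.16), with median scaling (-0.30) and with the median over probe sets (-0.19).

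Genes of red blood cells varied more than those of any brain cell type listed. The erythroid list had a median log2 deviation of 0.83 in sample 1 and -1.25 in sample 3, and the median SD of its 4 analysed genes was 4.04 times that of the trend. The alpha-globin gene Hba-a1 gave 10256, 9251, 3629.8 and 6998 units in samples 1 to 4 (7534 ± 2938, SD, n = 4), and the beta-globin gene Hbb-b2 gave 3658, 1557, 859 and 1477 units. Alas2, the first enzyme of heme synthesis in erythroid cells, gave 209.7, 237, 36.6 and 152 units, while the erythroid factor Klf1 ranged only from 80.8 to 127 units. Adjusted over the list alone, 3 of 4 genes passed the variance test. With no signal filter the list had 7 genes, most of the added ones near the floor, and its medians in samples 1 and 3 were 0.03 and -0.03, no longer apart from random lists. Choroid plexus, vessel and meningeal genes, which mark tissue that borders the hippocampus or runs through it, did not stand apart in any sample. Sample 3 had a choroid plexus median of -0.51, at the 0.525th percentile, and the thyroxine carrier Ttr gave 2629.5, 1236, 954 and 1820.2 units, the only 1 of 5 choroid plexus genes past the test adjusted over the list alone. Kl gave 152, 202, 138 and 247 units, and Folr1 gave 174, 146 and 128 units in samples 1, 2 and 4 and was below the floor in sample 3. Among vessel genes, with medians from -0.24 to 0.24, Pecam1 gave 114, 113, 80.8 and 168 units and Cldn5 gave 446, 259.9, 261 and 185 units. Among meningeal genes, with medians from -0.15 to 0.17, Dcn was lowest in sample 2 (723, 343, 869 and 813 units), Col1a2 stayed between 1099.8 and 1220.1 units, and Col1a1 was highest in sample 4, at 319 units.

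**Figure D3:**
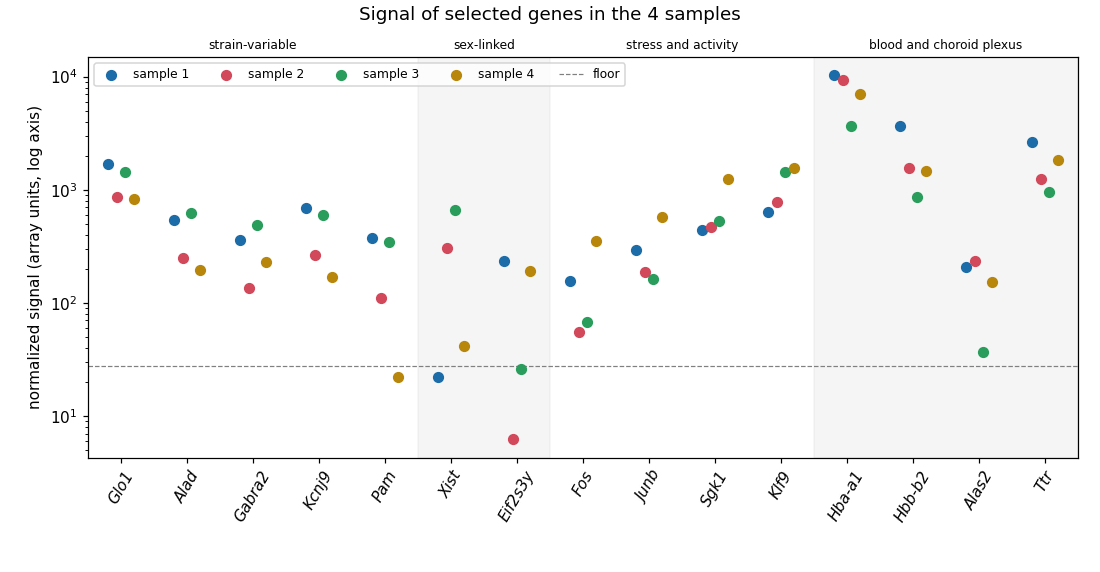
Normalized signal (array units, log axis) of 15 genes named in the text, with 1 point per sample and no error bars; the dashed line is the floor of 27.7 units, below which values have no order. The points of samples 1 and 3 lie above those of samples 2 and 4 for Glo1, Alad, Gabra2, Kcnj9 and Pam, and sample 4 lies highest for Fos, Junb, Sgk1 and Klf9.

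Neuronal genes were slightly higher in sample 1 than in the others. Of 16 analysed pan-neuronal genes, 14 were above the mean of the other samples in sample 1, with a median log2 deviation of 0.25 (1.19-fold), and 12 were below it in sample 4, with a median of -0.22 at the 0.615th percentile, inside the central 99%. The synaptic vesicle calcium sensor Syt1 gave 2039.9, 1160.2, 718 and 605 units in samples 1 to 4, and Syn2 gave 1962, 1092, 1382 and 1013 units. Map2 and Nefm, of the neuronal cytoskeleton, were lowest in sample 4, where they lay 3.34-fold and 3.08-fold below the mean of the other samples. Sample 4 also had the highest 3' to 5' ratio for 4 of 5 control transcripts, and 89 probe sets, those of Nefm and Camk2a among them, lay far below every other sample in it, against 12 to 18 such probe sets in samples 1 to 3. The synaptosomal protein gene Snap25 differed little between the samples, with 8316 ± 799 units (SD, n = 4). Past the variance test adjusted over the list alone were 0 of the 16 pan-neuronal genes. Genes of glutamatergic principal cells had medians from -0.11 to 0.05 and no sample apart, but their spread was wider than in 99% of random lists, 1.47 times the trend. Camk2a, a kinase subunit of excitatory synapses, gave 357, 629.7, 321 and 29.4 units, the last close to the floor of 27.7 units, and Camk2b gave 4628 ± 433 units (SD, n = 4). Adjusted over the list alone, 1 of 14 genes passed, Camk2a. This wide spread was no longer called without sample 1 (0.39), sample 2 (0.56) or sample 3 (0.14), or with no signal filter (0.66), values that are log2 ratios to the trend.

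Interneuron genes had medians from -0.15 to 0.05 with no sample apart. The GABA transporter gene of synaptic vesicles, Slc32a1, gave 376, 1074, 272 and 1139 units in samples 1 to 4, and was the only 1 of 10 genes past the test adjusted over the list alone. Gad1, which makes GABA in the same cells, gave 2067 ± 254 units (SD, n = 4) and was highest in sample 3. The hippocampal subfield genes had medians from -0.09 to 0.18, with Calb1 at 592 ± 69.9 units and Dsp, a granule cell marker, at 310.3 ± 78.1 units (SD, n = 4). The neuropeptide list had medians from -0.06 to 0.05, with Npy at 796 ± 133 and Sst at 2809 ± 355 units (SD, n = 4), and Tac2 at 66.3 to 161 units.

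Oligodendrocyte and myelin genes were high in sample 2 and low in sample 3, with medians of 0.28 and -0.37 over 11 analysed genes. In sample 3, 10 of the 11 were below the mean of the other samples, and in sample 2, 8 were above it. In sample 4, 8 were above it as well, with a median of 0.21 at the 96.6th percentile, inside the central 99%. The myelin genes Mog, Mal and Mag gave 185, 239, 157 and 219.7 units, 654, 930.1, 575 and 992 units, and 528, 818, 425 and 403 units in samples 1 to 4. Myelin basic protein (Mbp) gave 3629.8, 4760.1, 3397 and 4883 units, Qdpr was highest in sample 2 at 2856 units, and Cryab was lowest in sample 3 at 86.2 units. The high value no longer stood apart without sample 3 (0.18), nor the low value without sample 2 (-0.24). Past the variance test adjusted over the list alone were 0 of the 11 genes. Astrocyte genes did not stand apart, with medians from -0.13 to 0.17. Gfap was highest in sample 4 (827, 876, 581 and 1320.2 units), whereas the water channel Aqp4 (603, 739, 994 and 532 units) and the glutamate transporter Slc1a2 (189.7, 219, 373 and 107 units) were highest in sample 3. Microglial genes had medians from -0.23 to 0.08 with no sample apart, with Csf1r at 547 ± 77.2, Cx3cr1 at 277 ± 42.8 and C1qb at 293 ± 99.2 units (SD, n = 4).

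Chaperone genes were low in sample 2 and high in sample 3, by medians of -0.23 and 0.20 over 16 analysed genes. In sample 3, 15 of 16 were above the mean of the other samples, and 0 of 16 passed the variance test adjusted over the list alone. The inducible Hspa1a gave 265, 293, 356 and 239 units in samples 1 to 4, Hspa1b gave 213, 185, 257 and 226 units, and Hspa5, of the endoplasmic reticulum, gave 1017, 771, 1166 and 579 units. Dnajb1 gave 298, 216, 296 and 168 units and Pdia3 gave 277, 179.6, 265 and 151 units. In sample 2, Pdia4, Cct2 and Cct3 gave 169, 157 and 528 units, each the lowest of the 4 samples. The low value was lost without sample 1 (-0.18), and the high value without sample 2 (0.12) or without the signal filter (0.17). The list of interferon and MHC class I genes was low in sample 2, with a median of -0.53 over 4 analysed genes, and its spread was 2.20 times the trend. H2-D1 gave 735, 318, 628 and 376 units, H2-K1 gave 845, 478, 678 and 498 units, and Irf7 ranged from 82.7 units in sample 2 to 174 units in sample 4, while B2m was highest in sample 2 (470.5, 718, 331 and 300.4 units). H2-D1 and H2-K1 also belong to the strain-variable list, and their probe sets can also detect related class I genes. The median in sample 2 was 0 with no signal filter, and it was no longer apart with the median over probe sets (-0.37), without sample 1 (-0.44) or without sample 4 (-0.03). The wide spread was lost with no filter (0.69), with the median over probe sets (0.22), without sample 1 (0.76) and without sample 2 (0.52). Of the 4 interferon and MHC class I genes, 0 passed the variance test adjusted over the list alone.

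Genes of basic cell functions and of neighbouring brain regions did not stand apart in any sample. The 25 analysed genes of oxidative phosphorylation had medians from -0.01 to 0.05, and 19 of them spanned less than 1.5-fold, with Cox5b at 2354 ± 193 units (SD, n = 4) and Cox4i1 at 159.7 to 327 units. The 23 ribosomal protein genes had medians from -0.01 to 0.07, with Rpl13a at 358 ± 60.3 and Rpl10a at 1371 ± 153 units (SD, n = 4), and with Rps4l at 137 to 340.4 units. Clock genes had medians from -0.07 to 0.14, with Per1 at 263, 285, 334 and 422 units, Per3 at 289, 214, 346 and 183 units, and the output factor Dbp at 91.5, 278, 299.9 and 191 units in samples 1 to 4. Genes of neurogenesis and proliferation had medians from -0.20 to 0.12, with Dcx at 190.1 ± 28.6 units (SD, n = 4), Sox11 at 153 to 341 units and Nes at 58.7 to 205 units. Genes of the striatum had medians from -0.26 to 0.19, with Penk at 724 ± 136, Drd2 at 104 ± 6.36 units (SD, n = 4) and Pdyn at 108 to 200.2 units. Genes of the neocortex had medians from -0.31 to 0.32, with Tbr1 at 569 ± 122, Fezf2 at 500.1 ± 44.2 and Mef2c at 315 ± 60.6 units (SD, n = 4). Genes of the thalamus and habenula had medians from -0.14 to 0.35. Among them Nnat gave 4359, 1522, 2987 and 1234 units and was the only 1 of 7 genes past the test adjusted over the list alone, Tcf7l2 gave 407, 269.9, 172 and 339 units, and Prkcd stayed between 439.6 and 528 units. The pituitary hormone list had 3 analysed genes, too few for a test, with Prl at 109.5 ± 28.1 and Gh at 205 ± 15.8 units (SD, n = 4).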

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

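The test of 3' to 5' ratios was chosen after the result was seen, and so was the definition of probe sets that were low in a single sample; the other probe sets of the same genes were widened, after a first result was seen, to include those that were low as well. In 99 sets of 4 values, 6 had a sample that lay far from the others by Dixon's ratio, the gap to the nearest sample divided by the whole range. For sets not chosen by their values, chance gives about 1 in 20, or 4.95. Many of these sets were genes named for a large range or deviation, so that rate is only a rough guide here.

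Sst was high in sample 2, at 3339.6 units against 2599 to 2676 units in the others (ratio 0.884). Col1a1 was high in sample 4, at 319 units against 182 to 192 units (ratio 0.900). Drd2 was high in sample 4, at 114 units against 100.1 to 102 units (ratio 0.863), a 1.12-fold gap. Rpl10a was low in sample 4, at 1144 units against 1426 to 1479.7 units (ratio 0.858). Folr1 was low in sample 3, at 12.4 units, below the floor, against 128 to 174 units (ratio 0.835).

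The mean distance of sample 4 to the other samples, 0.29 log2 units, stood apart from the 0.24 to 0.25 of samples 1, 2 and 3 (ratio 0.939). Sample 4 also had 89 probe sets that lay at least 1 log2 unit below every other sample, with that gap more than 2 times the range of the others, against 18, 12 and 17 such probe sets in samples 1, 2 and 3; among the named genes, Camk2a and Nefm were of this kind. Of the 78 genes named by these probe sets, 26 had another analysed probe set, and in these as a group a drop of like size was not borne out. Their 29 other probe sets had a median log2 deviation of 0.0424 in sample 4 (95% bootstrap interval -0.0591 to 0.231), far from the drop of -1.76. Of the 29, 12 were lower and 17 higher in sample 4, and the second probe set of Camk2a dropped as well. This pooled median does not decide for single genes. The dropped probe sets were picked for an extreme fall, so a smaller fall in some of these genes stays possible. For the other 52 genes, which have a single analysed probe set, lower abundance and an uneven probe response cannot be told apart. Less complete RNA or cDNA stays open as a candidate explanation, since 4 of 5 control transcripts had their highest 3' to 5' ratio in sample 4. Of these 4, 1 is a ribosomal RNA, and for pyruvate carboxylase sample 3 came close. By Dixon's ratio, sample 4 did not lie far from the others for any of the 5 transcripts. No position of a probe set along its transcript was used to test this explanation. The labels state no condition for sample 4, so no biological explanation was tested. The identifier of sample 4, of a meaning not given, lies apart in number from the other 3, so a difference in processing order or batch stays open and untested.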

How the results depend on the processing

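The alternative without further normalization was chosen after the data had been seen. No probe set passed the variance test under any alternative, the omission of each sample included. The number of probe sets that ranged at least 2-fold was 2810 with no signal filter and 225 above the 75th percentile of signal, where more and fewer probe sets were tested, and it ran from 457 without sample 4 to 735 without sample 2. The mean over pairs of samples of the median absolute log2 difference was 0.26, and 0.210 above the 75th percentile of signal; it ran from 0.219 to 0.270 when 1 sample was left out. The number of list and sample pairs that stood apart, 17, was 11 of 104 with no signal filter, where genes near the floor enter, and ran from 10 without sample 1 or sample 3 to 14, with fewer samples to compare. The number of lists with a wide spread, 5, ran from 3 without sample 1 or sample 3 to 6. The median of the interferon and MHC class I list in sample 2 went from -0.53 to 0 with no filter; the cause was not tested. Of 22 calls on lists, 12 were kept under each alternative other than leaving out a sample, and 6 also when each sample was left out. The range of a named gene moved by more than 1 SD in 9 of 576 cases over the alternatives and in 70 of 384 cases when a sample was left out. No paired analysis was possible because there is only 1 group. Signal over background limits genes near the floor of 27.7 units, and a range that involves a value below it is a lower bound.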

Other observations

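The neighbour test that follows was set before its result was seen, and the interval of its number was added after. The tests of the strain-variable list, of remaining probe sets and of vessel genes, and the definition of a split, were chosen after the values they concern were seen.

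Several genes outside the lists separated the samples widely, and they were chosen after their values were seen. Pdxdc1 gave 734, 54.1, 759.6 and 26.1 units in samples 1 to 4 with 1 probe set, while 2 other probe sets had the opposite split, with 16.9, 342, 16.8 and 373 units and with 21.6, 303, 42.0 and 248 units. Prdx2, a peroxide-reducing enzyme, gave 124, 546, 196 and 560.2 units, and Srp9, of the signal recognition particle, gave 257, 1034, 261 and 1013 units. Lipoprotein lipase (Lpl) gave 193, 54.2, 179 and 54.1 units with 1 probe set and 392, 118, 349 and 167 units with another. The noncoding RNA genes Snhg6 (134, 649.8, 122 and 612 units) and Snhg11 (271, 826, 185 and 800.4 units) were also low in samples 1 and 3. Dynll2, a dynein light chain, gave 3694, 4397, 3645 and 618 units, and the 14-3-3 protein gene Ywhag gave 667, 513, 435 and 18.2 units, both low in sample 4 only. The smallest adjusted p among these genes was 0.356 (limma variance test), so none was past the threshold.

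Among 53 probe sets with a middle gap of at least 1 log2 unit that was more than 2 times the gaps within each pair of samples, 39 separated samples 1 and 3 from samples 2 and 4, 10 separated samples 1 and 4, and 4 separated samples 1 and 2. Inherited sequence variants in linked blocks were predicted to place such genes near one another, which was not detected. Of 27 genes with the main split, 2 had another such gene among the 5 nearest analysed genes on either side. This number lay inside the 95% range of random draws, 0 to 5, with a mean of 1.43. Its exact binomial 95% interval, 0.246 to 6.56, reaches beyond the range. Being neighbours is mutual, so the genes are not independent and the interval is only approximate. With so few genes, neither such variants nor a batch is excluded. In the strain-variable list, examined after this result, 9 of 11 genes had both of samples 1 and 3 on one side of samples 2 and 4 (7 higher, 2 lower), against 38.0% of all 4824 genes, above the upper end of 8 for the largest number over the 3 ways to pair the samples in random lists, and 51 of 10000 random lists reached as many; the list had already stood apart along this split in each sample, so this number restates that and decides nothing between a batch and inherited differences. Inherited differences at these genes, as between strains that differ at scattered loci, may be a candidate explanation, but it was found from the same values, and a batch of arrays or of RNA preparation that acts unevenly on genes stays open. Xist and Eif2s3y did not follow this split, being high in samples 2 and 3 and in samples 1 and 4.

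The analysed immediate early and glucocorticoid-responsive genes were high together in sample 4, with 22 of 27 up and a joint median log2 deviation of 0.53. Listed genes too low for analysis were mixed in direction there. More vessel-wall tissue in sample 4 stays open: the vessel list had a median of 0.24 with a 95% bootstrap interval from -0.46 to 0.284, below the joint median, but 5 of its 9 genes were up and 4 down, and the gap of 0.29 is smaller than their SD of 0.46. An uneven response of single probe sets stays open: the 4 remaining probe sets of these lists were also higher in sample 4 in 4 of 4 cases, with a median at the 99.49th percentile of random sets of like signal, but 4 probe sets are too few to decide. The labels state no handling, time of day or treatment, so no biological explanation, such as arousal or stress before tissue collection, was tested.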
